A study of Arabidopsis thaliana with 8 samples.

How the data were processed

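RNA from 8 samples of Arabidopsis thaliana was measured on single-colour Affymetrix arrays. Per the labels, 14-day-old wild-type and arr1,10,12 seedlings were placed for 1 h in liquid medium with 10 µM benzyladenine (BA) or DMSO, the roots were discarded by the treatment protocol (the tissue label reads seedling), total RNA was isolated with a plant RNA kit and checked on a gel, and biotin-labelled targets were made by the standard protocol of the array's maker. The 2 genotypes and 2 treatments make 4 groups of 2 arrays, taken with their replicate numbers from the sample titles. Nothing in the labels says that the 2 samples of a group were separate cultures.

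The deposited value of a probe set on an array is a linear ratio with no unit of its own. That the authors' values are ratios was read from the numbers: 70.1% of the probe sets have a median over the 8 arrays within 0.005 of 1, and 6803 probe sets (29.9%) have a median below that range. The highest median is 1.0005. The first kind were divided by their own median, and the dim ones apparently by a floor that is the same on all arrays, which cancels in a difference between arrays. The program that summarised the probes, the scaling between arrays and any background correction are not given in the sources used here. Absolute levels, detection calls and signal over background were not analysed here. All 8 value columns matched a sample by name.

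The table holds 22810 probe sets. The 64 control probe sets were left out of the tests and used to describe the arrays, and 22746 were tested. Names came from a probe annotation that gives 1 gene for 13513 probe sets (59.4%), several for 503 and none for 8730, the last being unnamed here. Symbols were updated by gene ID through the RefSeq table of assembly TAIR10.1, in which 13436 of the 13513 were found, and 77 kept the file's name. The 13513 stand for 13356 genes, of which 146 have more than 1 probe set and are represented by the one with the highest mean. That rule was fixed for intensities, and a mean of ratios is not a level. With the lowest mean instead, chosen after the data had been examined, the named genes differed by 1 of 24 in 1 comparison (AT1G64500 in place of AT2G31110 under BA, 7 arrays). None of the 24 list genes and 5 of 380 family genes have more than 1 probe set. No coordinates are given, because the files name no genome build.

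The tests were limma (version 3.58.1, R 4.3.3) on the log2 of the deposited ratio, with 1 mean per group over all 8 arrays and empirical Bayes moderation. The design had planned log2(value + 32) for linear values. The values proved to be ratios near 1, where an offset of 32 shrinks the size of every log2 change. The scale without an offset was therefore chosen after they had been seen, and offsets of 1, 32 and 100 were run as alternatives. The offset of 32 does not by itself lower the number of calls. With 8 arrays it gave 17 in wild type, against 5 without an offset, and 22 under BA, against 32. The 5 contrasts were BA in wild type, BA in the mutant, their difference (the interaction), and the genotypes under DMSO and under BA. A probe set passed at an adjusted p under 0.05 (Benjamini-Hochberg over 22746). A second fit without mutant DMSO replicate 1 (7 arrays) had been planned as an alternative, and was chosen for reporting beside the first after the control probe sets had been seen. It has 3 residual degrees of freedom, against 4 with 8 arrays. The groups share 1 estimate of the spread, so the spread of that array enters the standard errors of all contrasts in the 8-array fit.

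The rule for named genes was fixed before the data were examined: up to 12 genes with the largest change in each direction among those that passed with arrays that did not overlap (threshold only for the interaction), the 5 with the lowest p where no named gene passed, all type-A response regulators, the 3 targeted genes, and up to 4 genes of every other list with the lowest p. In all, 22 lists (236 genes) were fixed, and 24 of these genes had a named probe set, in 11 lists. Lists with at least 3 named genes, the auxin early response and the root markers, were tested with camera (preset correlation 0.01, and with an estimated correlation). Families of genes picked by symbol were added later, since the lists were so thinly covered. Retention of the wild-type response was the share of its called probe sets with the same sign in the mutant, with an exact (Clopper-Pearson) 95% interval.

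The fits were tested on simulated data with independent normal noise and 200 changed probe sets. Each probe set had its spread from the 7-array fit, also for 8 arrays, scaled on each array by 1 factor for all probe sets. For BA in wild type, over 22746 probe sets, the 8-array fit recovered 19 of 100 changes of 1 log2 unit and 65 of 100 of 2 units with 0 false calls, and the 7-array fit 43 and 82 with 4 false calls. For BA in the mutant the 8-array fit recovered 27 and 67 with 14 false calls, and the 7-array fit 26 and 81 with 12. The 14 false calls were among 108 calls, a larger share than the threshold of 0.05 aims at. The simulation does not copy how mutant DMSO replicate 1 deviates at single probe sets, so it may overstate what the 8-array fit recovers. The precision of a log2 change was a median SE of 0.218 for each group comparison with 8 arrays and 0.164 for BA in wild type with 7.

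The file-name prefixes in the labels form 3 sets: all wild-type arrays, mutant DMSO replicate 1 alone, and the other 3 mutant arrays. Wild-type BA effects lie within 1 prefix, and the 7-array fit keeps the mutant BA effect within 1 prefix. Alternatives were other scalings, offsets, filters on dim probe sets, variance models, array weights, the replicate number or the prefix as a block, subsets of arrays, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.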

Results

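The series measured RNA levels on 8 single-colour Affymetrix Arabidopsis arrays in 14-day-old seedlings, with 2 arrays in each of 4 groups. Wild-type seedlings and seedlings of the arr1,10,12 mutant were held for 1 h in liquid medium with 10 µM benzyladenine (BA, a synthetic cytokinin) or with its solvent, DMSO. The tissue label reads seedling, whereas the treatment protocol says that roots were removed and shoots kept. ARR1, ARR10 and ARR12 are type-B response regulators, the transcription factors at the end of the cytokinin phosphorelay. The design asks which genes respond to BA, and which of those responses need the 3 regulators. The deposited values are ratios: 70.1% of the probe sets are given relative to their own median over the 8 arrays, and the dim remainder, which includes RR16 and ARR15, apparently relative to a common floor, so levels can be compared between arrays but not between genes. The median relative value of an array lay between 0.906 and 0.958.

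Of the 8 arrays, mutant DMSO replicate 1 stood apart. The median 5′ to 3′ ratio of relative values over its 6 pairs of GAPDH, ubiquitin and actin control probe sets was 0.352. On the log2 scale that was -1.51, against -0.01 to 0.15 on the other 7 arrays. As a quotient of relative values, it compares the arrays with one another and is not an absolute 5′ to 3′ ratio. Its value for the 25S ribosomal RNA control was 197, against 0.666 to 3.48 elsewhere. It differed more than 2-fold from its group mate in 17.9% of probe sets, whereas the arrays of the wild-type groups differed so in 0.747% (DMSO) and 0.972% (BA), and those of the BA-treated mutant in 3.34%. Each comparison is therefore given for all 8 arrays, the design fixed before the data were examined, and for the 7 arrays without this one. In the 7-array fit the DMSO-treated mutant is a single array (replicate 2), assumed to vary like the other groups. Those groups did not vary alike. The within-group SD (log2) was 0.211 (DMSO) and 0.199 (BA) in wild type and 0.305 in the BA-treated mutant. If the single array varies like the latter, the SEs of comparisons that use it are too small. Fold changes in wild type and between the BA-treated groups are identical in both fits, and only their standard errors (SE) differ. An SE is that of the 7-array fit unless 8 arrays are named. The number of arrays limits the precision of every value, and p-values measure only the spread between these samples, since no label says that the 2 arrays of a group came from separate cultures.

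**Figure D1:**
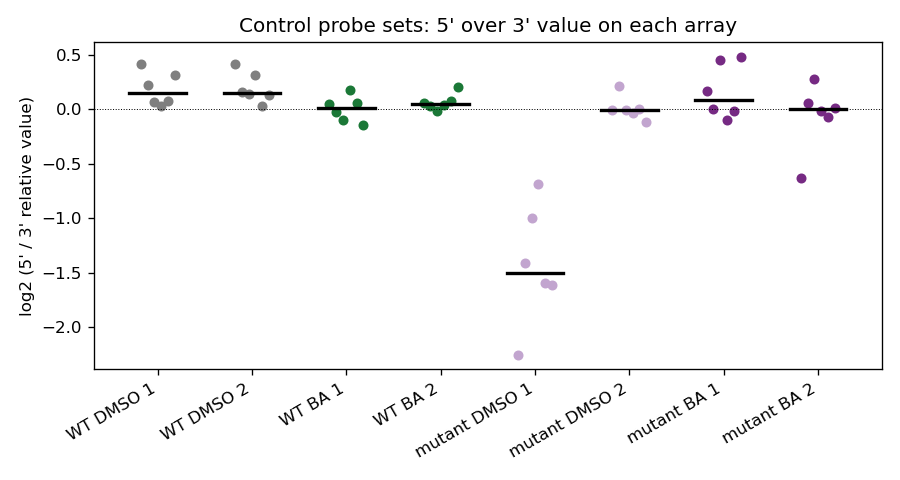
Log2 ratio of the relative value of the 5′ to that of the 3′ control probe set (vertical axis) on each of the 8 arrays (horizontal axis), with 1 point for each of 6 control pairs and a bar at their median. The median of mutant DMSO replicate 1 was -1.51 and those of the other 7 arrays lay between -0.01 and 0.15.

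The 3 targeted genes could not be followed. ARR1, ARR10 and ARR12 had 0 named probe sets among the 13513 probe sets to which the annotation gives a single gene, so the arrays labelled mutant were not checked at the disrupted genes. Of the other type-B regulators, RR18 and RR19 had named probe sets and neither passed the limma test in any comparison.

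In wild type, 1 h of BA raised 2 type-A response regulators, the rapidly induced genes that dampen cytokinin signalling. RR16 (ARR16) was 4.57-fold higher with BA (log2 change 2.19 ± 0.16, SE, 7-array fit) and ARR15 was 5.94-fold higher (2.57 ± 0.42). The relative values of RR16 were 0.926 and 0.783 with DMSO and 3.93 and 3.85 with BA. RR16 passed the limma test after Benjamini-Hochberg adjustment in both fits (adjusted p = 0.0324 with 8 arrays and 0.00583 with 7), and ARR15 in the 7-array fit (adjusted p = 0.0349, against 0.164 with 8 arrays). ARR15 was at 6.16 and 2.23 on the BA arrays, and its log2 change was 1.84 without BA replicate 1 and larger than 2.57 without BA replicate 2. Neither gene passed without either wild-type DMSO array (limma adjusted p = 0.0810 to 0.226, 7-array fit). UGT76C2, a cytokinin N-glucosyltransferase, was 2.56-fold higher but did not pass (adjusted p = 0.0893 in the 7-array limma fit), and UGT76C1 differed by -0.18 ± 0.26.

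Among named genes, the strongest decreases in wild type were larger in fold than the strongest increases. AT2G27420, which encodes a papain-like cysteine protease, fell 11.7-fold (log2 change -3.55 ± 0.22) and passed in both fits (limma adjusted p = 0.0324 and 0.00397). AT2G15020 fell 12.5-fold, AT5G42760 fell 11.3-fold, AT3G44450 fell 8.94-fold and the glutaredoxin-family gene AT1G64500 fell 8.04-fold, all in the 7-array fit. AT2G19650, AT1G55960, AT4G24700, AT1G65490, AT5G01740, AT3G56290 and AT2G41250 fell by 2.78 to 2.08 on the log2 scale in that fit. Among the increases, the cold-regulated chloroplast proteins COR15A and COR15B rose by 3.17 ± 0.41 and 2.51 ± 0.25, the acyltransferase gene AT5G47980 by 3.03 ± 0.25, and AT4G03610 by 2.46 ± 0.15 (limma adjusted p = 0.0324 with 8 arrays and 0.00397 with 7). AT2G29500, a small heat shock protein, rose by 2.46 ± 0.27, and AT5G48570 (ROF2), a peptidyl-prolyl isomerase, by 2.40 ± 0.44, just past the threshold (limma adjusted p = 0.0500, 7 arrays). UGT76E12, GSTU26, AT1G21550, AT2G41730 and AT3G01260 rose by 2.36 to 2.67 in the 7-array fit.

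In total, 5 probe sets passed in wild type with all 8 arrays (3 higher, 2 lower) and 516 with 7 arrays (192 higher, 324 lower), by limma with Benjamini-Hochberg adjustment. The 516 named 95 genes that rose and 155 that fell. Besides AT4G03610, RR16 and AT2G27420, the 5 held 2 probe sets without a gene name here, 264470_at (log2 change 3.49) and 253496_at (-2.97), picked after their values were seen because the count is small. The 4 wild-type arrays alone, which share a file-name prefix, gave 960 probe sets. The 8-array count of 5 was 0 without any 1 of the wild-type or BA-treated mutant arrays. The 7-array count was 0 without either wild-type DMSO array, 164 or 51 without wild-type BA replicate 1 or 2, and 960 without either BA-treated mutant array. Only 48.4% of the 516 carried a gene name, against 59.4% of all probe sets tested.

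**Figure D2:**
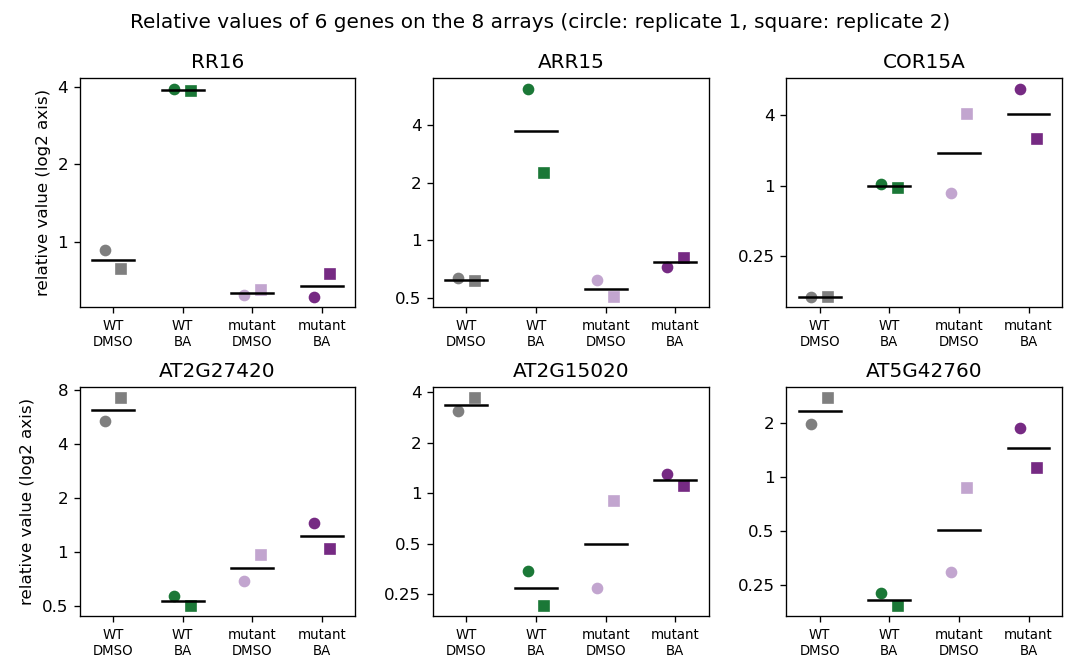
Relative values (vertical axis, log2 scale) of RR16, ARR15, COR15A, AT2G27420, AT2G15020 and AT5G42760 on the 8 arrays, by group (horizontal axis), with circles for replicate 1, squares for replicate 2 and a bar at the geometric mean. RR16 was at 3.93 and 3.85 in BA-treated wild type and between 0.609 and 0.926 on the other 6 arrays.

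The fixed lists covered little else of the wild-type response, since 24 of their 236 genes had a named probe set. Of the type-A response regulators, 2 of 2 rose in the 7-array fit. None of the 2 genes of cytokinin degradation and conjugation, 1 light harvesting gene (LHCB4.1), 2 genes of chlorophyll synthesis (CHLM, PORB), 2 of flavonoid and anthocyanin synthesis (DFR, UF3GT), 1 clock gene (GI) and 2 of the touch and rapid stress response (STZ, WRKY53) passed in wild type. Adjusted over the list alone, UGT76C2 passed as higher and CHLM, an enzyme of chlorophyll synthesis, as lower (-0.56 ± 0.17). With 2 named genes in each of these lists, that adjustment is little stricter than an unadjusted p under 0.05. Of the drought, cold and abscisic acid list, COR15A, its 1 named gene, rose. The 6 auxin early response genes and the 3 root markers held 0 genes that passed in wild type. A further 11 lists, from cytokinin receptors to heat shock, had no named gene.

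In the mutant, neither type-A regulator passed: the BA effect was 0.06 ± 0.20 for RR16 and 0.60 ± 0.51 for ARR15 (7 arrays). With 8 arrays 0 probe sets passed the limma test, and the lowest adjusted p was 0.488. In that fit 1215 had an unadjusted p under 0.05 where chance gives 1137. Array weights, which cannot tell which of 2 group mates deviates, also gave 0. The 5 named genes nearest to passing were AT1G10340, GRX480, AT3G09405, AT5G62130 and AT1G76600, and GRX480, a glutaredoxin, differed by -2.07 ± 0.26 with 8 arrays (limma adjusted p = 0.709). In the 7-array fit 8 probe sets passed, all lower with BA. The 5 with a name were AT5G56980 (-2.50 ± 0.22), AT1G22810 (-2.39 ± 0.19), an AP2/ERF transcription factor, AT3G02840 (-2.21 ± 0.20), and the calmodulin-like genes AT1G76640 (CML39, -2.10 ± 0.19) and CML37 (-2.08 ± 0.17), each with a limma adjusted p of 0.0413. These calls rest on mutant DMSO replicate 2, where AT5G56980 was at 4.99 against 0.372 on replicate 1. The other 3 probe sets have no gene name here: 247360_at (-3.39), 260405_at (-2.39) and 261037_at (-3.12). With replicate 1 kept in place of replicate 2, 5488 probe sets passed. The 7-array count of 8 was 0 without any 1 of the 4 wild-type arrays, 6 without mutant BA replicate 1 and 245 without mutant BA replicate 2.

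As a set, the probe sets called in wild type did not lie in the wild-type direction in the mutant. Of the 516 probe sets called in wild type (7 arrays), 218 had the same sign in the mutant, 42.2% with an exact 95% binomial interval of 37.9 to 46.6%, which treats probe sets as independent. The 192 that rose in wild type had a median log2 change of 1.33 there and -0.01 in the mutant, and the 324 that fell had -1.23 and 0.07. None of the 516 passed in the mutant in the wild-type direction, and 2 passed in the opposite direction. With 8 arrays 2 of the 5 called had the same sign.

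The difference between the genotypes in their BA response was tested directly. RR16 responded less in the mutant, by -2.13 ± 0.26 on the log2 scale (limma adjusted p = 0.0350 with 7 arrays, 0.168 with 8), whereas for ARR15 the difference of -1.97 ± 0.66 did not pass (adjusted p = 0.315 with 7 arrays). RR16 no longer passed this test without any 1 of the 4 wild-type arrays (adjusted p = 0.0941 to 0.189, 7-array fit). Of the genes that BA lowered in wild type, AT5G42760 (4.24 ± 0.44), AT3G44450 (4.23 ± 0.52), AT2G15020 (4.06 ± 0.39) and AT2G27420 (3.89 ± 0.35) had the largest positive differences, and AT2G19650, AT3G56290, AT4G24700 and AT1G65490 also passed. AT5G62130, AT1G13650, AT1G23205 and the cytochrome P450 gene CYP71B26 passed with positive differences of 2.08 to 2.50. Negative differences that passed included AT3G01830 (-3.49 ± 0.36), AT1G76640 (-3.08 ± 0.24), AT1G61890 (-3.04 ± 0.33), COR15B, AT3G05640, a protein phosphatase 2C gene, and AT1G11670, GRX480, AT3G44190, AT1G21550, AT2G32140, AT5G54170 and AT4G03610. AT3G01830, AT1G76640 and AT1G61890 were at 6.64, 3.60 and 2.42 on mutant DMSO replicate 2 and at 0.983, 0.867 and 0.782 on replicate 1. For AT5G42760, AT3G44450, AT2G15020 and AT2G27420 both mutant DMSO arrays lay below both wild-type DMSO arrays. A lower DMSO level in the mutant thus enters their positive differences. AT2G27420 was at 5.35 and 7.25 in wild type with DMSO and 0.568 and 0.498 with BA. On the mutant DMSO arrays it was at 0.687 and 0.966.

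By limma, 0 probe sets differed in their BA response with 8 arrays (1970 at an unadjusted p under 0.05, lowest adjusted p 0.113, 0 with arrayWeights, 18 with quantile normalization, 5 with the planned offset of 32) and 103 with 7 arrays (44 positive, 59 negative), which named 22 and 26 genes. Among the 516 wild-type calls 81 passed this test, all against the wild-type direction, a sign that the shared wild-type arrays favour. The count was 0 without either wild-type DMSO array or without wild-type BA replicate 2, 47 without wild-type BA replicate 1, 515 without mutant BA replicate 2, and, of the 8 arrays, 4732 with mutant DMSO replicate 1 in place of replicate 2.

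**Figure D3:**
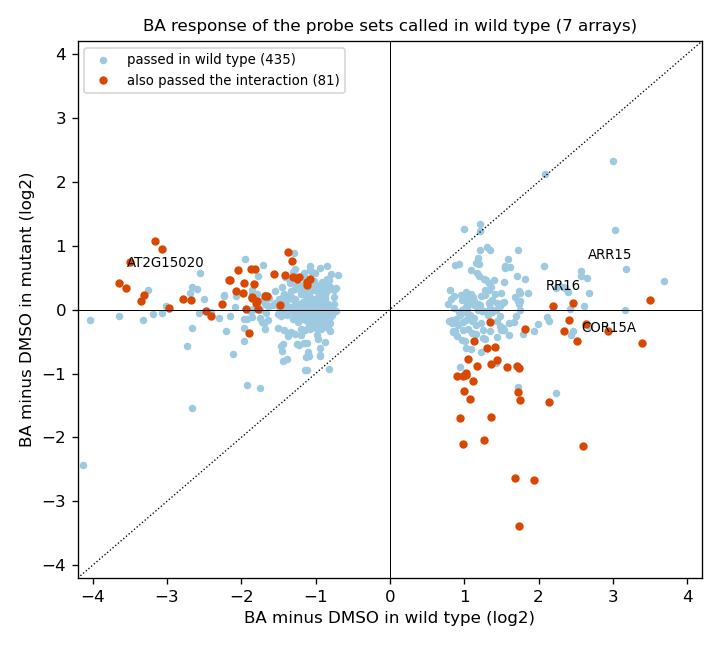
BA minus DMSO in the mutant (vertical axis, log2) against the same in wild type (horizontal axis, log2) for the 516 probe sets called in wild type in the 7-array fit, with the 81 that passed the test of the difference in orange and equal responses on the dotted line. Most points lie near 0 on the vertical axis, at a median of -0.01 for the 192 raised and 0.07 for the 324 lowered in wild type.

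Under DMSO, the mutant had more COR15A (5.21 ± 0.50, 7-array fit) and psbA, the plastid gene of a photosystem II core protein (3.55 ± 0.59), and less PDF1.2, a defensin of the jasmonate and ethylene response (-5.23 ± 0.85), than wild type. AT1G80130 (4.36 ± 0.54), AT2G38240 (4.44 ± 0.82), AT3G60290, AT5G62280, AT4G36700, AT3G01830, AT1G73040, AT3G55840, the homeobox gene HAT2 (3.00 ± 0.43) and the expansin-like gene EXLA2 (2.97 ± 0.44) were also higher. The genes lower in the mutant included AT5G37990, AT1G09500, AT1G64590, AT2G16005, AT1G14960, AT4G14060, AT5G38030, AT3G44450, M17, the cineole synthase gene TPS-CIN (-3.10 ± 0.39) and the caffeoyltransferase gene FACT (-3.09 ± 0.34). These genotype values rest on mutant DMSO replicate 2: HAT2 was at 5.55 there and at 0.236 on replicate 1, and COR15A at 4.12 and 0.872, against 0.111 on each wild-type DMSO array. All 24 genes named in the 7-array fit had a limma adjusted p of 0.00227 to 0.0371 there, and none passed with 8 arrays.

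With 8 arrays 2 probe sets differed under DMSO, both lower in the mutant, without a gene name here and picked after their values were seen, 264374_at (-3.54) and 253496_at (-3.48). The named genes nearest to passing were AT1G13650, AT2G27420, AT3G22210, AT1G55240 and JAL33, all lower (limma adjusted p = 0.0822 to 0.0861). With 7 arrays 961 probe sets differed (530 higher, 431 lower in the mutant), naming 272 and 230 genes, and quantile normalization turned that split to 208 higher and 420 lower. The count was 48 and 13 without wild-type DMSO replicate 1 and 2, 533 without either wild-type BA array, 1803 without either mutant BA array, and 5279 with mutant DMSO replicate 1 in place of replicate 2. All 4 wild-type arrays carry a file-name prefix that no mutant array carries, so genotype cannot be told apart from such a batch in this comparison or the next.

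Under BA, RR16 was lower in the mutant by 2.53 on the log2 scale (-2.53 ± 0.16, limma adjusted p = 0.0159 with 8 arrays and 0.00108 with 7). ARR15 (-2.27 ± 0.42) and UGT76C2 (-2.10 ± 0.31) were lower in the 7-array fit (limma adjusted p = 0.0251 and 0.0132). ARR15 no longer passed without either wild-type DMSO array (adjusted p = 0.0704) or mutant BA replicate 1 (0.0539), and UGT76C2 without wild-type BA replicate 1 (0.0603). Also lower in the BA-treated mutant with all 8 arrays were AT5G47980 (-4.49 ± 0.43, SE with 8 arrays) and AT4G03610 (-2.69 ± 0.18). This comparison shares the wild-type BA arrays with the BA effect in wild type, so genes called as raised there are favoured to be lower here. The other genes lower with 8 arrays, with SEs of that fit, were the dirigent-family genes AT4G11190 (-3.74 ± 0.38) and AT4G11210 (-2.49 ± 0.27), AT1G07050, AT3G45700, AT1G02360, AT3G59340 and AT4G16146. AT1G60060 was higher (1.62 ± 0.16, SE with 8 arrays).

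The 7-array fit added, on the higher side, DFR (5.27 ± 1.07), an enzyme of anthocyanin synthesis whose relative values of 101 and 7.54 differed widely between the 2 BA-treated mutant arrays, AT1G80130 (5.08 ± 0.44), SAG29 (3.35 ± 0.39), a SWEET sugar transporter, and AT1G70985, AT5G01740, AT5G22460, AT1G73040, AT1G69160, AT2G43140, AT2G19650, AT2G31110 and AT5G42760. AT2G31110 has 2 probe sets, which gave 2.96 and 2.39. On the lower side it added the defensins PDF1.2 (-4.42 ± 0.69) and PDF1.2b (-3.94 ± 0.69), AT5G48570 (ROF2, -3.67 ± 0.44), the small heat shock protein gene AT5G51440 (-3.62 ± 0.25), and AT1G64590, AT1G14960, AT1G14120, AT4G14060 and AT3G45710. On the BA-treated mutant arrays PDF1.2 was at 0.0215 and 0.121 and PDF1.2b at 0.0322 and 0.182. Whether these 2 probe sets read separate transcripts was not tested. In total 32 probe sets differed with 8 arrays (2 higher, 30 lower) and 1747 with 7 (937 higher, 810 lower, naming 452 and 407 genes), by limma with Benjamini-Hochberg adjustment. The median over all probe sets was 0.12 in this comparison, and the 7-array split was 760 higher and 900 lower after centring each array on its median and 642 higher and 938 lower after quantile normalization. With 8 arrays quantile normalization gave 27 higher and 112 lower. The 8-array count of 32 was 0 without any 1 of the wild-type arrays or mutant BA replicate 1, and 20 (12 higher, 8 lower, 4 of them among the 32) without mutant BA replicate 2. Array weights gave 623 higher and 607 lower, and the file-name prefix as a random block gave 0 probe sets. The 7-array count was 926 without either wild-type DMSO array and 717 or 328 without wild-type BA replicate 1 or 2.

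Among the fixed lists, 2 of 6 auxin early response genes passed as higher in the mutant under DMSO and 1 under BA, and of 3 root markers 0 passed under DMSO and 1 passed as lower under BA. All 6 auxin genes had positive values under DMSO (median 1.35, 7 arrays), of which IAA29 (2.64 ± 0.43) and WES1 (2.25 ± 0.42), an auxin-conjugating enzyme, passed and GH3.3 did not (3.35 ± 0.70, limma adjusted p = 0.0521). Adjusted over the list alone, 3 of the 6 passed. Camera, the limma test of a list against all other genes, gave an adjusted p of 0.00104 under DMSO, and 0.156 with an estimated correlation. IAA29 was at 4.85 on mutant DMSO replicate 2 and at 0.726 on replicate 1, and with 8 arrays the list's median was 0.57 (camera adjusted p = 0.0453, and 0.00104 to 0.923 over its alternatives). Under BA the median was 0.63, with 1 gene passing (WES1, 2.05 ± 0.35), a camera adjusted p of 0.0129, and an adjusted p of 0.179 with an estimated correlation. With BA in the mutant the 6 values were negative (median -0.31, camera adjusted p = 0.0148 with 7 arrays), none passed, and the adjusted p was 0.313 with an estimated correlation. That median was 0.24 without mutant BA replicate 1 and 0.64 without mutant DMSO replicate 2 when taken from the 8 arrays.

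The 3 root markers were the root-hair expansins EXPA7 and EXPA18 and the root beta-glucosidase PYK10. All had negative values in the mutant, with medians of -1.40 under DMSO and -1.31 under BA in the 7-array fit, and PYK10 passed under BA (-1.10 ± 0.16, limma adjusted p = 0.0127). Adjusted over the list alone, all 3 passed under both treatments. The camera adjusted p was 0.00151 under DMSO and 0.000911 under BA, and with an estimated correlation the adjusted p was 0.156 and 0.179. The treatment protocol says that roots were removed before RNA extraction, while the tissue label reads seedling, and the values do not settle which holds. Among the smaller lists, 1 of 2 genes of flavonoid and anthocyanin synthesis (DFR) was higher under BA, and adjusted over the list alone 2 of 2 (UF3GT, 3.88 ± 0.92, at 19.5 and 1.98 on the BA-treated mutant arrays). COR15A was higher in the mutant under both treatments (2.04 ± 0.41 under BA). In lists with 2 named genes, adjusting over the list alone is little stricter than an unadjusted p under 0.05. STZ, of the touch list, was at 1.97 on mutant DMSO replicate 2 and 0.304 on replicate 1, against 0.656 and 1.06 in DMSO-treated wild type. WRKY53, of the same list, was at 1.72 and 1.12 on these mutant arrays, against 0.684 and 0.544 in DMSO-treated wild type. None of the light harvesting, chlorophyll, clock and touch genes passed between genotypes, although adjusted over the list alone STZ and WRKY53 passed as higher under DMSO and PORB as higher under BA. UGT76C2 passed as lower under DMSO adjusted over the list alone.

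**Figure D4:**
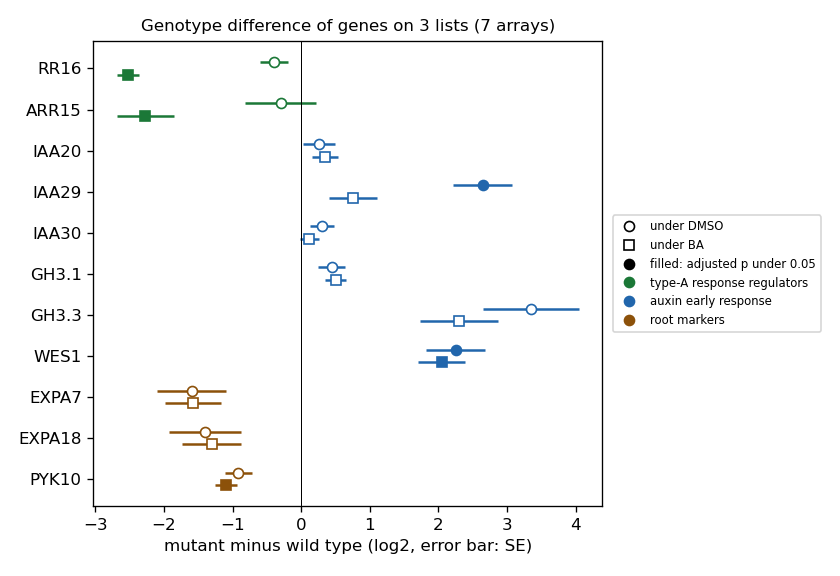
Mutant minus wild type (horizontal axis, log2, with SE bars) in the 7-array fit for 2 type-A response regulators, 6 auxin early response genes and 3 root markers (vertical axis), with circles under DMSO, squares under BA and filled symbols past an adjusted p of 0.05. RR16 and ARR15 were lower under BA (-2.53 and -2.27), and all 3 root markers had negative values under both treatments.

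Gene families picked by symbol after the data had been seen gave further groups. Of 47 UDP-glycosyltransferase genes, 5 rose with BA in wild type (UGT76E12, UGT76E11, UGT73B5, UGT73B4 and UGT84A4, by 1.04 to 2.44) and 0 fell (camera adjusted p = 0.0297, 7 arrays; adjusted p = 0.919 with an estimated correlation). In the BA-treated mutant 5 were higher and 13 lower than in wild type, and the family did not pass (camera adjusted p = 0.0683, and adjusted p = 0.704 with an estimated correlation). Its median there was 0.00, and -0.06 and -0.05 after median centring and quantile normalization. The 69 plastid-encoded genes had a median BA effect of 0.22 in wild type, with 0 passing (camera adjusted p = 0.0172, and adjusted p = 0.919 with an estimated correlation). Under DMSO their median was 0.53 higher in the mutant, with psbA and ycf3 passing (camera adjusted p = 0.0103, and adjusted p = 0.721 with an estimated correlation). Among 8 calmodulin-like genes, CML37 and AT1G76640 fell with BA in the mutant and differed in response between the genotypes (camera adjusted p = 0.00383 and 0.00861, and adjusted p = 0.432 and 0.692 with an estimated correlation). Of 9 plant U-box genes 8 had positive values in the mutant under DMSO (median 0.75) and PUB23 passed, and their median with BA in the mutant was -0.49 (camera adjusted p = 0.0169 and 0.00425, and adjusted p = 0.721 and 0.432 with an estimated correlation). Of 13 glutathione transferase genes 1 was lower in the mutant under DMSO (median -0.36, camera adjusted p = 0.0169, and adjusted p = 0.721 with an estimated correlation). The plastid-encoded genes had a median of -0.13 with BA in the mutant and -0.43 for the difference in response, with 0 passing (camera adjusted p = 0.0391 and 0.00081, and adjusted p = 0.771 and 0.692 with an estimated correlation). Apart from that of the glycosyltransferases under BA, these medians kept their sign after quantile normalization and after median centring. These calls for families under DMSO, with BA in the mutant and for the difference in response rest, on the mutant DMSO side, on mutant DMSO replicate 2 alone. On that array the 25S ribosomal RNA control was at 3.48, against 0.666 to 1.44 on the wild-type and mutant BA arrays. Among the plastid genes, psbA was at 5.64 on mutant DMSO replicate 1 and 2.90 on replicate 2, against 0.159 and 0.385 in DMSO-treated wild type. Whether the plastid values depend on the quality of the RNA was not tested.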

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

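The tests of mutant DMSO replicate 1 and of the missing BA response described here were chosen after those patterns had been seen.

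A difference in BA response between the genotypes was found by test in 103 probe sets (7 arrays). The next genes were picked from the named genes by direction, not by that test: with all 8 arrays, the BA and DMSO arrays did not overlap in either genotype and lay in opposite order. Some of them, such as AT2G27420 and GRX480, are among the genes given above as passing that test with 7 arrays. The order counts mutant DMSO replicate 1, the array that stood apart. For AT1G64500, AT2G19650, AT3G56290 and AT1G69160, mutant DMSO replicate 2 lay nearer to both mutant BA arrays than to replicate 1. For AT5G62130, AT3G09405 and AT1G76600 the 2 mutant DMSO arrays lay nearer to each other than to either mutant BA array. With 2 arrays per group such an order can also arise by chance. With 8 arrays the limma test of the difference passed for 0 probe sets (1970 at an unadjusted p under 0.05). Differences in log2 response, mutant minus wild type with 8 arrays, were positive for AT2G27420 (4.14), AT5G62130 (2.63), AT1G13650 (2.33), AT1G23205 (2.29), AT3G22210 (1.04), AT2G15020 (4.92), AT5G42760 (5.02), AT1G64500 (4.07), AT2G19650 (3.92), AT3G56290 (3.82) and AT1G69160 (3.92). They were negative for GRX480 (-3.01), AT3G09405 (-2.17), AT1G76600 (-1.59), AT1G02360 (-1.63), COR15B (-3.58), AT2G29500 (-3.65), AT1G21550 (-3.37), AT3G05640 (-3.43), AT3G44190 (-3.50), psbA (-3.99) and AT1G14120 (-1.53). Without mutant DMSO replicate 1 the difference was smaller in size for AT2G15020, AT5G42760, AT2G19650, AT3G56290, COR15B and AT3G44190, among others, and larger for AT1G13650.

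Control probe sets, which no comparison used, were above 2 times the highest wild-type DMSO value on some arrays. The 25S ribosomal RNA control was at 197 on mutant DMSO replicate 1 and 3.48 on replicate 2, and the 5S control at 3.34 on mutant BA replicate 1. The bioC hybridisation controls were at 2.77, 2.75 and 2.69 on mutant DMSO replicate 1, and a dap control at 1.99 on wild-type BA replicate 2.

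Mutant DMSO replicate 1 stood apart from the other 7 arrays. A difference in scale alone is argued against. Quantile normalization lowered the spread of its group from 0.592 to 0.471 on the log2 scale, still above the 0.210 to 0.310 of the other groups. Whether it was exchanged with another group of the series cannot be decided from correlations. The array's highest correlation of deviations with an array of another group was 0.0147, but with its own group mate it was -0.376. The other pairs of group mates reached 0.305 to 0.654, so the array resembled neither its own group nor another. Shortened RNA or cDNA is a candidate explanation: the array's median 5′ to 3′ ratio of relative control values was -1.51 (log2) against -0.01 to 0.15 on the others. A single wrong label or a separate run stays open, since no other array carries its file-name prefix.

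The wild-type response to BA was not seen in the mutant. Larger noise of the mutant arrays is argued against: 400 probe sets chosen on the wild-type replicate 1 pair moved by a median of 1.35 in the wild-type direction in the held-out wild-type pair. In the mutant that median was 0.0166 (95% bootstrap interval over probe sets -0.03 to 0.08) and -0.04 for the BA arrays against DMSO replicate 2, but -0.84 and -0.66, opposite to wild type, against DMSO replicate 1. Whether the mutant already stood at the treated level under DMSO was examined in a separate choice of 400. These were chosen on both wild-type BA arrays against wild-type DMSO replicate 1. Signed by the wild-type response, mutant DMSO replicate 2 lay 0.0884 from wild-type DMSO replicate 2 (-0.02 to 0.31), and replicate 1 lay 0.946 (0.76 to 1.15). For probe sets that BA raises the values were -0.15 on replicate 2 and 0.15 on replicate 1. The held-out wild-type pair of the first choice gave 1.28, so these values argue against a treated level under DMSO for the raised probe sets. For those that BA lowers the values were 0.41 on replicate 2 and 1.70 on replicate 1. There the question stays open, because the 2 DMSO arrays differ. Loss of the 3 response regulators, the difference the design names, is consistent with these values but was not tested at the genes themselves, 0 of which had a named probe set, and file-name prefix and genotype cannot be told apart.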

How the results depend on the processing

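Choices made after the data had been examined were the reported scale without an offset, in place of the planned offset of 32, leaving out the dim (floored) probe sets, the crossed pairing, and all alternatives of the 7-array fit. Unless a reason is given, the cause of a change was not tested. Signal over background could not be used here, so what dim signals limit is unknown.

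With 8 arrays, the counts in wild type, for the interaction, under DMSO and under BA (5, 0, 2 and 32) became 116, 18, 105 and 139 with quantile normalization. They became 12, 0, 2 and 61 with an offset of 1, and 17, 5, 0 and 19 with 100. With the planned offset of 32 they were 17, 5, 1 and 22, with 3 of the 5 in wild type and 11 of the 32 under BA among them. With a trended, robust variance they were 0, 1, 14 and 28. Array weights gave 809, 0, 2 and 1230. They cannot tell which of 2 group mates deviates, and the median log2 changes stayed those of the unweighted fit (-0.011 for BA in the mutant). The file-name prefix as a random block (consensus correlation 0.575) gave 116, 0, 0 and 0. Leaving out the dimmest 30% gave 51 under BA. The 4 wild-type arrays alone gave 960, the 4 DMSO arrays 0 and the 4 BA arrays 926. In the mutant the count was 0 under all of these, and median centring changed no count by over 1.5 times.

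The labels do not say whether equal replicate numbers pair the samples. Correlations of same-numbered deviations between groups ran from -0.174 to 0.124. They show no clear pairing, but weak correlations cannot settle whether samples were handled in pairs. With the replicate number as a block (replicate block) the counts were 0, 0, 0, 0 and 0. With the wild-type numbers crossed they were 1 in wild type, 0 in the mutant, 0 for the interaction, 0 under DMSO and 11 under BA, and the share of the wild-type response with the same sign in the mutant was 100% of that 1.

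Leaving out 1 array at a time with 8 arrays, counts ranged from 0 to 516 in wild type, 0 to 5488 in the mutant, 0 to 4732 for the interaction, 0 to 5279 under DMSO and 0 to 1747 under BA. The same-sign share ranged from 25.2% to 42.2% and the list tests passing from 2 to 6. The highest counts of probe sets all came without mutant DMSO replicate 1 or 2, and the 6 list tests passing came without mutant BA replicate 1. No same-sign share could be formed where the wild-type count was 0. Of 10 list tests 4 passed with 8 arrays and 5 with 7, 0 and 0 with an estimated correlation, and with 8 arrays 2 without the dimmest 30% and 2 without the floored probe sets.

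With 7 arrays, quantile normalization gave 1 probe set in the mutant and 628 under DMSO. Without the floored probe sets 5 passed in the mutant, and with a trended, robust variance 4. Leaving out a further array, counts ranged from 0 to 960 in wild type, 0 to 245 in the mutant, 0 to 515 for the interaction, 13 to 1803 under DMSO and 328 to 2263 under BA. The same-sign share ranged from 42.7% to 51.0% and the list tests passing from 4 to 7.

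Directions reversed only near 0 or without particular arrays. The auxin median for the interaction (0.06 with 8 arrays) became -0.097 with quantile normalization, -0.0012 with median centring, -0.000268 and -0.000823 with offsets of 100 and 32, and -0.19 to 0.49 on leaving out 1 array. Its values were -0.0208, -0.189 and -0.152 without wild-type BA replicate 1, mutant DMSO replicate 1 and mutant BA replicate 2. With BA in the mutant the auxin median ranged from -0.31 to 0.64 (0.24 without mutant BA replicate 1, 0.64 without mutant DMSO replicate 2). The root median with BA in the mutant ranged from -0.65 to 0.54 with 8 arrays (0.29 without mutant DMSO replicate 1, 0.54 without mutant BA replicate 2) and from -0.34 to 0.92 with 7 (-0.34 without mutant BA replicate 1). For the interaction it ranged from -0.84 to 0.24 with 8 arrays (0.0185 and 0.24 without the same 2 arrays). With 7 arrays it ranged from -0.53 to 0.69 and was -0.017 with median centring, -0.11 without wild-type DMSO replicate 2, -0.22 without wild-type BA replicate 1 and -0.53 without mutant BA replicate 1.

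Without mutant DMSO replicate 2, values with BA in the mutant reversed for AT5G56980 (-2.50 to 1.24 on leaving out 1 array) and AT1G22810 (-2.39 to 0.65). Under DMSO they reversed for AT5G62280 (-2.23 to 3.33), AT4G36700 (-0.18 to 3.26), HAT2 (-1.56 to 3.00), EXLA2 (-0.028 to 2.97), IAA29 (-0.10 to 2.64) and WES1 (-0.79 to 2.25). Over all genes named and all alternatives, 2141 values kept their direction and side of the threshold with 8 arrays, 342 newly passed, 148 no longer passed and 8 reversed. With 7 arrays 1005 kept both, 325 no longer passed and 0 reversed.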

Other observations

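The test of the median of additional root-expressed genes was set down before their values were seen. The tests of array runs and of these genes as a set were chosen afterwards.

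Further root-expressed genes had negative values in the mutant, of which 2 passed under BA. Of 29 further genes known from roots, root hairs and the thalianol cluster, 7 had a named probe set, and all 7 had negative values under BA in the 7-array fit: AT2G47540 (-0.83), AT5G06630 (-0.22), AT5G04960 (-1.62), AT3G49960 (-1.40), AT4G26010 (-1.50), the cellulase gene GH9C1 (-0.97) and AT1G30870 (-1.21). AT5G04960 and GH9C1 passed the limma test (adjusted p = 0.0380 and 0.0491). The median was -1.21 under BA and -2.03 under DMSO (-1.39 with 8 arrays). Camera gave p = 7.86e-05 under BA (7 arrays), and p = 0.173 with an estimated correlation of 0.703 between these genes, so as a set they did not pass. Their median BA effect in wild type was 0.26.

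Less root tissue in the mutant samples is a candidate explanation, as a hypothesis: it needs the further root genes to be lower as well, and their median was -1.21 with an SD of 0.48 between genes. The treatment protocol says that roots were removed and the tissue label reads seedling, so what was extracted is not settled, and absolute levels, which would show how much of these transcripts comes from shoot cells, were not analysed here. A difference between array runs could give the same picture, since 0 file-name prefixes hold both genotypes. A lower activity of these genes in mutant tissue stays open and was not tested.

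The genes that BA lowered in wild type differed between the arrays in another way. The 200 probe sets with the largest decrease in the wild-type replicate 1 pair had medians, relative to wild-type DMSO replicate 2, of -1.43 on wild-type BA replicate 2, -1.55 on mutant DMSO replicate 1, -0.34 on mutant DMSO replicate 2, and -0.22 and -0.26 on the mutant BA arrays. The 200 with the largest increase had medians of 1.28, 0.07, -0.14, -0.41 and -0.13 on the same arrays. Wild-type DMSO replicate 1, which was used in the choice, had medians of 0.14 for the decreased and -0.31 for the increased probe sets. Mutant DMSO replicate 1 is the array with the low 5′ to 3′ control ratio (-1.51, log2), so its -1.55 may not reflect the untreated mutant.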
